A study of Mus musculus with 9 samples.

How the data were processed

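RNA sequencing measured gene expression in 9 mouse samples that form 3 groups of 3. The sham group is healthy colon, the model group is tumour tissue from mice given saline, and the AC group is tumour tissue from mice given Astragalus and Curcuma phaeocaulis. Per the labels' protocols, RNA was extracted with Trizol and libraries were built with the VAHTS Universal V6 kit. The aligner, the read length and the strand setting of the counting are not given in the sources used here. Groups were taken from the treatment and tissue given for each sample, and replicate numbers from the sample titles. The descriptions do not say that the 3 samples of a group came from separate animals, so all p-values measure only the spread between these samples, which may be technical.

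The authors deposited a table of raw read counts per gene, made with featureCounts 1.5.0-p3 and the genome build mm9, per the submitters' processing notes. It holds 56398 features, of which 54446 have an Ensembl mouse gene identifier and 1952 have an identifier of the authors' own that starts with the word for new. The authors also deposited FPKM values, which are these counts divided by gene length and by the total count of the sample. The gene length implied by counts and FPKM lay within 1% of the summed exons in GENCODE M21, an annotation of build GRCm38, for 96.3% of 17737 genes with at least 20 counts. The build named in the notes and the gene models behind the counts therefore differ, and all coordinates given here are GENCODE M21 positions on GRCm38. Symbols were paired with 54409 identifiers through the same annotation, and 37 were not paired.

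Total counts per library ran from 15690038 to 23476056, so 3 counts, used as the floor for a gene that was not detected, correspond to 0.128 to 0.191 CPM (counts scaled to library size). Fold bounds in model tumours against colon used TMM-scaled library sizes, with a mean floor of 0.211 CPM in sham and 0.125 CPM in model libraries. Intervals (95%) and floors cover counting error only, because reads without molecular identifiers are not independent molecules. No pair of libraries in a group was identical, and all pairs differed by more than sampling noise.

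From the counts, each pair of groups was tested on its own 6 libraries with edgeR 4.0.16 in R 4.3.3: TMM scaling, filterByExpr at its default settings, a robust quasi-likelihood fit (glmQLFit and glmQLFTest) and Benjamini-Hochberg adjustment, with a threshold of 0.05 on the adjusted p. Values per gene are CPM scaled by TMM within each comparison, so that a group's value differs between comparisons, given as mean and SD over 3 libraries, and fold changes are log2 with their SE. The 32 gene lists were tested with camera in limma 3.58.1 on voom-weighted log2 CPM with a preset correlation of 0.01, for lists with at least 5 tested genes, and adjusted over the lists. Camera with an estimated correlation and fry were run beside it. List levels per library are means of log2(CPM + 0.5) over the members. The tests, the alternatives, the gene lists and the rule for naming genes were set before the data were examined, apart from the alternatives and lists said to be later.

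By that rule, genes were named from those with a symbol (no Gm number, Rik name or pseudogene suffix), a mean of at least 5 CPM in the higher group, an adjusted p past the threshold and groups that did not overlap. The 8 with the largest rise and the 8 with the largest fall were taken, or, where none passed, the 5 with the smallest p in each direction. Up to 3 members with the smallest adjusted p represent each list, or the 1 with the smallest p where no member passed. The text uses some of these, and list members outside the rule appear as examples of their list, chosen after their values were seen. Genes in families of close copies, overlapping genes and antisense genes are given as uncertain, since their reads may be shared.

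The tests were tried on simulated counts drawn from the means and library sizes of these samples, in 5 simulations of 200 changed genes for each comparison. For AC against model tumours, over 16789 genes, edgeR recovered 15.2% of genes changed 1.5-fold, 50.4% of those changed 2-fold, 76% at 4-fold and 91.6% at 8-fold, and 9.6% of the calls were false. For model tumours against colon, over 17594 genes, the shares were 0.8%, 4.8%, 48% and 78.8%, with 8.1% false calls. For AC tumours against colon, over 17281 genes, they were 0.4%, 3.2%, 47.2% and 75.6%, with 7.3% false calls. In the data, 12697 and 12165 genes were called in these comparisons with colon, far more than the 200 changed here. The adjusted threshold is then looser, so the simulated shares do not give the recovery in the data against colon. Camera with the preset correlation found the raised list, which mixed genes raised 1.5-fold and 4-fold, in 5 of 5 simulations of each comparison. It gave p under 0.05 for 2%, 3.2% and 3.6% of unchanged lists in AC against model, model against sham and AC against sham. Simulated genes varied independently and unchanged lists were random, so these shares do not cover lists whose members vary together. Estimated correlations within the real lists reached 0.97 (epithelial identity, AC against model).

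Alternatives set in advance were median-of-ratios size factors (RLE), no low-count filter, a filter of at least 1 CPM in at least 3 libraries, DESeq2 1.42.0, all 9 libraries in one fit, the replicate number as a block, and limma-trend on log2(FPKM + 1) and log2(FPKM + 0.1) of the deposited FPKM, for genes with an FPKM of at least 1 in at least 3 libraries. A fold threshold of 1 on the log2 scale, a fit that was not robust and each library left out in turn were also tried. Chosen after seeing the data were upper-quartile factors, no factors beyond library size, an adjusted p under 0.1, model tumour 1 and AC tumour 3 left out together, and the colonocyte level of each library as a covariate. No column of sample values was left unused, and no gene was left out other than by the filters.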

Results

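The data are RNA-seq gene counts from mice into which CT26 cells, a mouse colon carcinoma line of BALB/c origin, had been injected, and from healthy colon. The sham group held 3 samples of healthy colon, the model group 3 tumours from mice given saline, and the AC group 3 tumours from mice given Astragalus and Curcuma phaeocaulis, herbs of traditional Chinese medicine, mixed 2:1, at 6 g/kg once a day. Total counts were 16078471, 17162962 and 19932103 in the sham libraries, 23476056, 19485636 and 16495522 in the model libraries, and 17900328, 15690038 and 16084532 in the AC libraries. Between 24356 and 27784 features were detected per library. Mitochondrially encoded transcripts took 7.59% ± 0.9 of the counts in colon (SD, n = 3), 2.39% ± 0.09 in model tumours and 2.5% ± 0.13 in AC tumours. The largest shares belonged to mt-Co1 (4.69% ± 0.23), Car1 (1.21% ± 0.37) and Lypd8 (1.19% ± 0.06) in colon. In model tumours they belonged to Eef1a1 (1.34% ± 0.06), mt-Co1 (1.1% ± 0.05) and Fn1 (0.52% ± 0.09), and in AC tumours to Eef1a1 (1.33% ± 0.07), mt-Co1 (1.18% ± 0.07) and Ahnak (0.44% ± 0.03).

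Libraries of the same group differed in tissue markers. Sham 1 had 304 CPM of Ms4a1, a B cell surface protein, against 30.7 and 13 in sham 2 and sham 3, and 44.8 CPM of Myh11, the smooth muscle myosin heavy chain, against 485 and 537. Sham 2 and sham 3 were much closer to each other (chi-square per degree of freedom 3.06) than either was to sham 1 (100.45 and 118.84), while pairs of tumours of a group lay between 10.19 and 28.66. Epcam, an epithelial adhesion protein, measured 36.1 CPM in model tumour 1 and 68 in AC tumour 3, at most 0.952 in the other 4 tumours, and 2790 to 2910 in colon. Muc2, the main colonic mucin, was at 72.1 CPM in model tumour 1 and 84.2 in AC tumour 3, against 262, 459 and 465 in colon. Over 16967 genes, the first principal component (90.4% of the variance) parted colon from tumours, the second (4%) parted sham 1 from the other sham libraries, and the third (2.6%) parted model tumour 1 and AC tumour 3 from the other tumours.

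**Figure D1:**
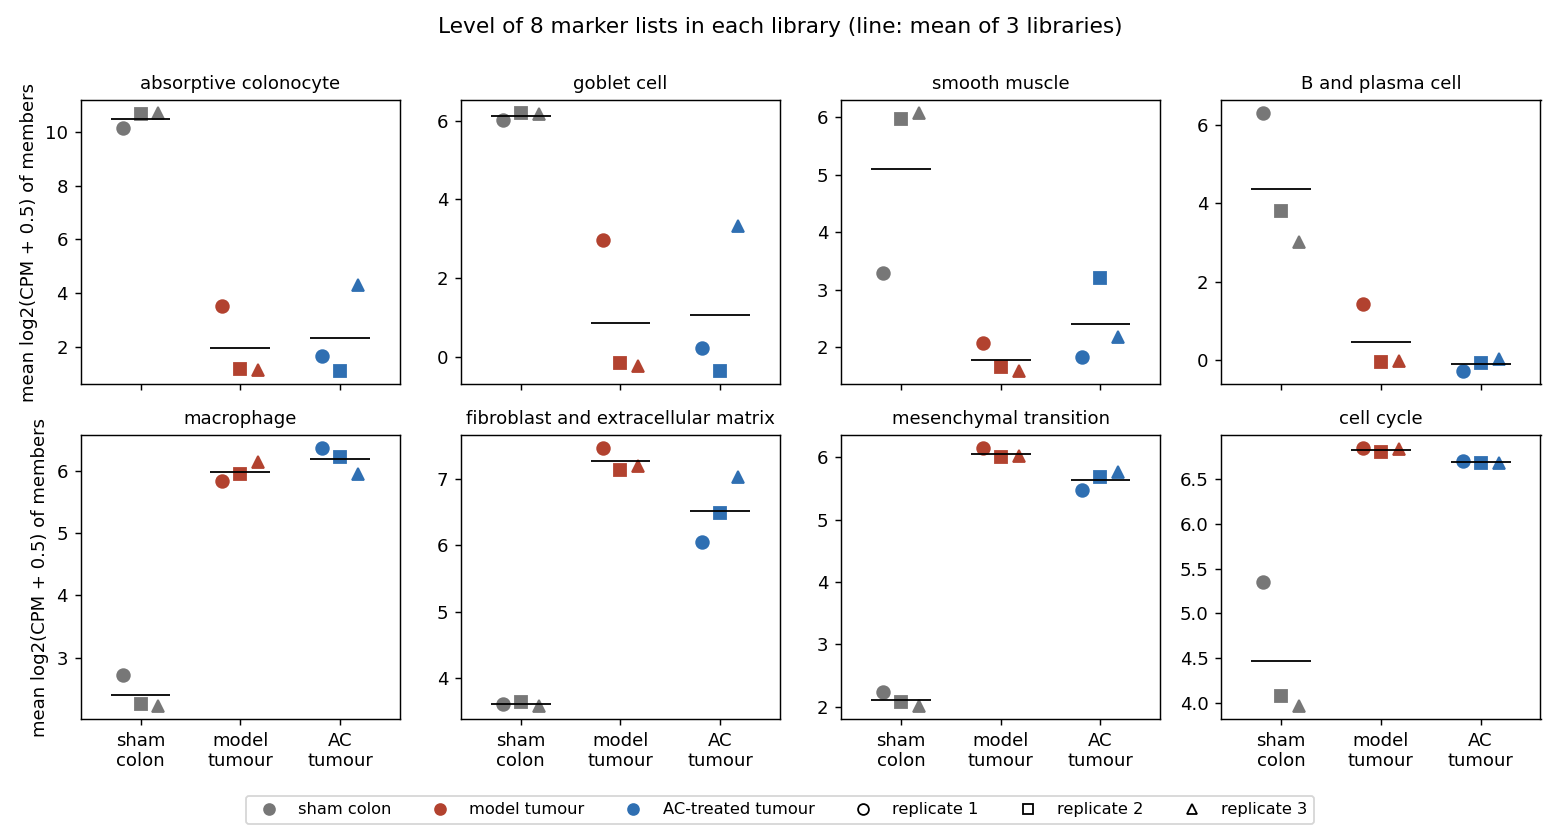
Level of 8 marker lists in each of the 9 libraries, as the mean log2(CPM + 0.5) of the members on the vertical axis, with the group on the horizontal axis, a point per library and a line at the mean of 3 libraries. Goblet cell transcripts lie at 2.97 in model tumour 1 and 3.32 in AC tumour 3 against -0.36 to 0.22 in the other 4 tumours, and B and plasma cell transcripts at 6.3 in sham 1 against 3.79 and 3.01 in the other sham libraries.

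Model tumours were compared with healthy colon to ask how the injected tumours differ from normal tissue. Transcripts of the colonic epithelium and of energy metabolism fell, and those of macrophages, extracellular matrix, mesenchymal regulators and cell division rose as lists by camera with the preset correlation, calls that were lost with an estimated correlation (adjusted p = 0.532 for each). Slc9a3, the apical sodium-proton exchanger of colonocytes (ENSMUSG00000036123, chromosome 13, 74121457 to 74169442), went from 342.5 ± 109.5 CPM in colon to 0.0728 ± 0.0586 in tumours (SD, n = 3 each), a log2 fold change of -12.15 (SE 0.542, edgeR adjusted p 1.96e-05). Vim, the intermediate filament of mesenchymal cells, went from 35.3 ± 17.8 to 3581 ± 393 CPM (6.67, SE 0.442, adjusted p 4.92e-05), and Msr1, a macrophage scavenger receptor (ENSMUSG00000025044, chromosome 8, 39581685 to 39642673), from 4.19 ± 0.274 to 140.8 ± 17.5 CPM (5.07, SE 0.166, adjusted p 1.44e-05).

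All 14 absorptive colonocyte genes fell, over all genes tested and adjusted over the list alone (median log2 fold change -8.5, camera adjusted p 5.79e-06). Car4, a membrane carbonic anhydrase, went from 628 ± 106 to 0.72 ± 0.235 CPM, and the keratin Krt20 from 4980 ± 406 to 197 ± 35.7 CPM. Of 12 goblet cell genes, 9 fell and 3 were not called, and 10 fell when adjusted over the list alone (median -4.67, camera adjusted p 0.000908). Clca1, a secreted component of mucus, went from 174 ± 48.3 to 11.3 ± 2.61 CPM. All 14 epithelial identity and junction genes fell by both counts (median -7.47, camera adjusted p 4.6e-05), among them Cdh1, the epithelial cadherin, from 1285 ± 96.7 to 9.29 ± 12.7 CPM. The 6 tested enteroendocrine genes fell by both counts (median -4.71, camera adjusted p 0.0109), and Chgb, a granin of secretory granules, went from 15.8 ± 2.67 to 0.238 ± 0.266 CPM. With an estimated correlation, adjusted p = 0.532 for each of these 4 lists. Model tumour 1 stood above the other model tumours in these lists, with an epithelial identity level of 3.65 against 0 and 0.02 on the log2 scale, and an absorptive colonocyte level of 3.52 against 1.16 and 1.14.

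Genes of energy metabolism were lower in tumours. All 13 oxidative phosphorylation genes fell by both counts (median -1.59, camera adjusted p 4.14e-05), although 1 of them lay above 0 without scaling factors. Cox5a, a subunit of cytochrome c oxidase, went from 226 ± 4.03 to 24.4 ± 0.726 CPM. Of 12 genes of fatty acid oxidation and PPAR signalling, 10 fell and 2 rose by both counts (median -3.59, camera adjusted p 0.00514). Angptl4, a secreted lipase inhibitor, rose from 0.961 ± 0.307 to 49.7 ± 1.56 CPM. The fatty acid transporter Cd36 was the other gene that rose, from 4.1 ± 0.975 to 21.8 ± 5.92 CPM. With an estimated correlation, adjusted p = 0.532 for both lists. Of 12 xenobiotic and NRF2 genes, 9 fell and 3 rose by both counts, and the list was not called (median -1.67, camera adjusted p 0.058). Hmox1, the heme-degrading oxygenase, rose from 4.31 ± 1.58 to 125 ± 13 CPM, while Srxn1, a sulfiredoxin, fell from 257 ± 7.08 to 67.4 ± 4.61 CPM.

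Stromal and mesenchymal lists moved the other way. Of 14 fibroblast and extracellular matrix genes, 13 rose and Postn fell, by both counts (median 4.14, camera adjusted p 0.000331). Fn1, fibronectin, rose from 43.2 ± 24.7 to 4268 ± 930 CPM, and Col1a1, a chain of type I collagen, from 9.49 ± 0.244 to 139.9 ± 38 CPM. Postn, the matrix protein periostin, fell from 29.7 ± 2.11 to 5.27 ± 0.918 CPM. The mesenchymal transition list had 13 of 14 genes higher and 1 not called, by both counts (median 4.53, camera adjusted p 4.14e-05). Twist1, a transcription factor of mesenchyme, rose from 0.48 ± 0.272 to 44.8 ± 7.52 CPM, and Cdh2, the neural cadherin, from 1.69 ± 0.601 to 74.4 ± 7.61 CPM. Of 12 endothelial genes, 10 rose and 2 were not called, by both counts (median 2.27, camera adjusted p 0.0109), and Cdh5, the vascular cadherin, rose from 2.04 ± 1.12 to 41.5 ± 5.79 CPM. All 18 cell cycle genes rose by both counts (median 2.17, camera adjusted p 0.000253), with Ccnb1, cyclin B1, going from 15.7 ± 10.2 to 127 ± 11.2 CPM. With an estimated correlation, adjusted p = 0.532 for each of these 4 lists. Among the sham libraries, sham 1 stood closest to the tumours in the cell cycle list, with a level of 5.35 against 4.07 and 3.96, and 6.8 to 6.85 in model tumours.

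**Figure D2:**
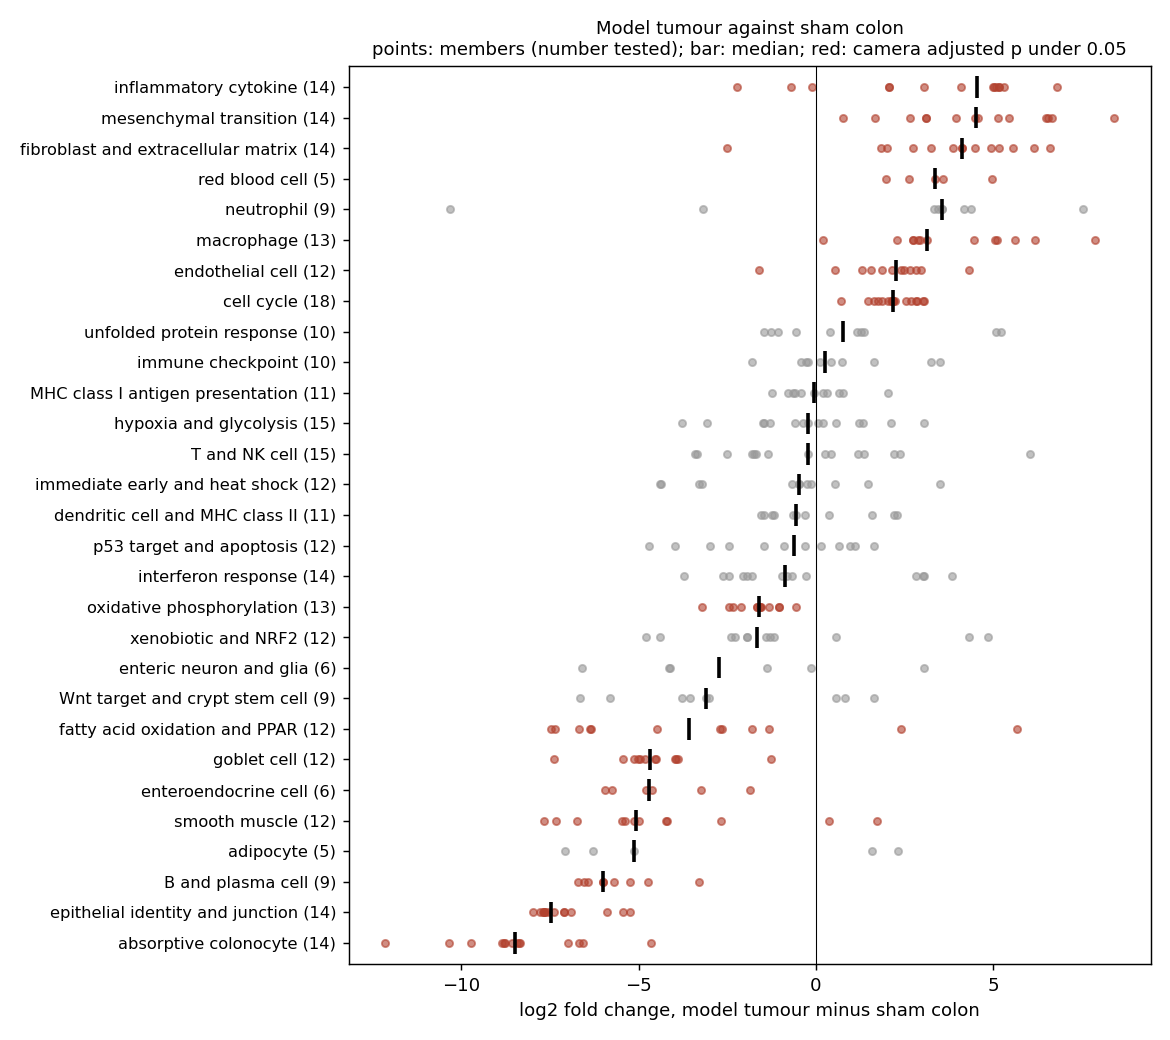
Log2 fold change of each tested member of the gene lists, model tumours minus healthy colon (horizontal axis), with a point per gene and a line at the list median; members with 0 counts in a group are drawn at their bound. Medians run from -8.5 for absorptive colonocyte genes to 4.56 for inflammatory cytokine genes.

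The immune lists differed by cell type. Of 13 macrophage genes, 12 rose and 1 was not called, by both counts (median 3.14, camera adjusted p 0.000292). Mrc1, the mannose receptor, rose from 4.91 ± 0.676 to 242 ± 90.9 CPM, and Arg1, arginase 1, from 1.6 ± 1.145 to 116 ± 12.9 CPM. Of 14 inflammatory cytokine genes, 11 rose, 1 fell and 2 were not called, by both counts (median 4.56, camera adjusted p 0.0155), with 1 member changing sign without scaling factors. Ptgs2, the inducible cyclooxygenase, rose from 5.24 ± 0.995 to 171 ± 27.9 CPM, and Ccl2, a monocyte chemokine, from 0.687 ± 0.892 to 76.1 ± 21.8 CPM. Tnf, tumour necrosis factor, fell from 8.81 ± 3.69 to 1.88 ± 0.212 CPM. With an estimated correlation, adjusted p = 0.532 for both lists. Of 9 neutrophil genes, 7 rose and 2 fell by both counts, and the list was not called (median 3.57, camera adjusted p 0.196). Mmp9, a gelatinase of neutrophil granules, rose from 1.47 ± 0.665 to 14.9 ± 2.32 CPM. Ly6g, a neutrophil surface protein from a family of close copies whose value is therefore uncertain, fell from 77.7 ± 26 to 0.0539 ± 0.0647 CPM.

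Of 9 B and plasma cell genes, 8 fell and 1 was not called, and all 9 fell when adjusted over the list alone (median -6.01, camera adjusted p 0.0409, and adjusted p = 0.627 with an estimated correlation). Jchain, the joining chain of secreted antibodies, went from 193 ± 176 to 2.96 ± 2.36 CPM. The list was at 6.3 in sham 1 against 3.79 and 3.01 in the other sham libraries. It was not called without model tumour 2 (camera adjusted p 0.0651) or model tumour 3 (0.0659), where single libraries left out gave 0.01 to 0.0659. Of 12 smooth muscle genes, 10 fell, Hspb6 rose and Smtn was not called, by both counts (median -5.06, camera adjusted p 0.0409, and adjusted p = 0.659 with an estimated correlation). Mylk, the myosin light chain kinase, fell from 247 ± 83.9 to 38.4 ± 7.29 CPM, and Hspb6, a small heat shock protein, rose from 3.72 ± 1.69 to 12.5 ± 0.656 CPM. The smooth muscle level was 3.29 in sham 1 against 5.96 and 6.07 in the other sham libraries. That list was not called without model tumour 1 (0.0654), model tumour 2 (0.0567) or model tumour 3 (0.0512). Its camera adjusted p was 0.000645 without sham 1, where the colon group was only sham 2 and sham 3. Those libraries were far closer to each other than to sham 1, so that value may rest on too small a spread in colon. All 5 tested red blood cell genes rose by both counts (median 3.6, or 3.38 with Hba-a2 at its bound, camera adjusted p 0.0467, and adjusted p = 0.532 with an estimated correlation), and the list was not called without sham 1 (0.0934, over a range of 0.00858 to 0.0934). Alas2, the first enzyme of heme synthesis in red cells, rose from 0.133 ± 0.127 to 4.58 ± 0.992 CPM, while the globin genes are close copies and uncertain.

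Other immune lists were not called and had members on both sides. Of 15 T and NK cell genes, 4 rose, 6 fell and 5 were not called, by both counts (camera adjusted p 0.865). Their median of -0.22, mean of -0.15 and camera direction were negative while fry was positive, and the median was 0.4 without scaling factors. Prf1, perforin, rose from 0.527 ± 0.237 to 34.6 ± 5.45 CPM, while Cd3e, a chain of the T cell receptor complex, fell from 8.36 ± 1.52 to 3.26 ± 0.381 CPM. Of 14 interferon response genes, 4 rose, 9 fell and 1 was not called, by both counts (median -0.88, camera adjusted p 0.196), with 1 changing sign without scaling factors. Gbp2, an interferon-inducible GTPase with close copies, rose from 26 ± 5.88 to 216 ± 18.9 CPM, while Isg15, a ubiquitin-like modifier, fell from 154 ± 10.6 to 24.9 ± 2.54 CPM. Of 11 MHC class I genes, 3 rose, 4 fell and 4 were not called, by both counts (camera adjusted p 0.812). They had a median of -0.04, a mean of 0.03, a negative camera and a positive fry direction, and medians of 0.01 with upper-quartile factors and 0.58 without factors. Nlrc5, the transactivator of MHC class I genes, rose from 29.8 ± 2.72 to 122 ± 21.1 CPM. Of 11 dendritic cell and MHC class II genes, 3 rose, 2 fell and 6 were not called, by both counts (camera adjusted p 0.839). The median was -0.55 and the mean -0.04, fry was positive, and the median without scaling factors was 0.04. Itgax, the integrin CD11c, rose from 4.46 ± 0.719 to 13.5 ± 3.83 CPM. Of 10 checkpoint genes, 3 rose and 7 were not called, by both counts (median 0.27, camera adjusted p 0.512), and 3 changed sign without scaling factors. Havcr2, the receptor TIM-3, rose from 1.74 ± 1.69 to 16.7 ± 1.48 CPM. The call of Foxp3, the regulator of regulatory T cells (log2 fold change 1.64, adjusted p 0.0199), was lost without sham 2 (0.077), sham 3 (0.0744), model tumour 1 (0.0552) or model tumour 2 (0.0681).

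The remaining lists were not called or had fewer than 5 tested genes. Of 15 hypoxia and glycolysis genes, 4 rose, 6 fell and 5 were not called, by both counts (median -0.22, or 0.4 without scaling factors, camera adjusted p 0.632). Bnip3, a mitophagy receptor, rose from 17.1 ± 3.22 to 141.5 ± 32 CPM, and Hk2, hexokinase 2, fell from 890.0 ± 134 to 106 ± 11.5 CPM. Of 12 p53 target genes, 4 rose, 6 fell and 2 were not called, by both counts (median -0.6, or 0.01 without scaling factors, camera adjusted p 0.357), and Fas, the death receptor, fell from 49.2 ± 0.842 to 6.25 ± 0.771 CPM. Of 10 genes of the unfolded protein response, 6 rose and 3 fell, or 4 fell when adjusted over the list alone (median 0.78, camera adjusted p 0.632), with 1 changing sign without scaling factors. Asns, asparagine synthetase, rose from 6.26 ± 3.17 to 215 ± 37.5 CPM. Of 12 immediate early and heat shock genes, 2 rose, 4 fell and 6 were not called, by both counts (median -0.48, or 0.14 without scaling factors, camera adjusted p 0.28). Fos, an immediate early transcription factor, went from 188 ± 14.4 to 8.89 ± 1.97 CPM. Of 9 Wnt target and crypt genes, 6 fell, 2 rose and 1 was not called, by both counts (median -3.1, camera adjusted p 0.155), and Lgr5, a receptor of crypt stem cells, fell from 6.2 ± 0.644 to 0.0572 ± 0.0316 CPM. Of 6 enteric neuron and glia genes, 3 fell and 1 rose by both counts, with 1 changing sign without scaling factors (median -2.73, camera adjusted p 0.155), and of 5 adipocyte genes 3 fell and 1 rose by both counts (median -5.12, camera adjusted p 0.526). Neither of 2 skeletal muscle genes was called, 1 of 2 keratinocyte genes rose (Sbsn, suprabasin, 1.88, adjusted p 0.0269, not called without sham 3, 0.102, or model tumour 2, 0.0862), and the 1 tested acinar gene, Cela1, fell from 21.4 ± 0.445 to 3.78 ± 1.11 CPM.

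The largest rises by the naming rule were in genes with 0 counts in every sham library, so their fold changes are lower bounds against a floor of 3 counts per library. Irx2 and Irx1, neighbouring homeobox genes, reached 27.8 ± 1.27 and 16.4 ± 0.818 CPM, at least 132-fold and 77.6-fold higher. Klk10, a kallikrein-related peptidase, reached 39.4 ± 28 CPM (at least 187-fold higher). The long noncoding RNA Lncenc1 reached 43.5 ± 22 CPM (at least 206-fold higher). Gzmg (chromosome 14, 56156582 to 56159579) and Gzme, granzymes from a cluster of close copies and so uncertain, reached 64.2 ± 3.02 and 22.9 ± 2.37 CPM, at least 304-fold and 109-fold higher. Among the largest falls beside Slc9a3, Cfap65 (53 ± 36.4 CPM in colon, at least 425-fold lower), Slc5a9, a sugar transporter (20.7 ± 4.57), and Prap1 (20.7 ± 5.55, both at least 166-fold lower) had 0 counts in all model tumours. Btnl6, a butyrophilin-like gene, stood at 165 ± 39.7 CPM in colon and had 3 counts in all model tumours, a ratio of 4060 (95% counting interval 1390 to 19700). Uncertain for shared reads were Sprr2a2 at 254 ± 170 CPM in colon (1 count in tumours, ratio 19200, 3440 to 758000), Clca4b at 332 ± 410 (2 counts, 11500, 3200 to 95300) and the antisense gene Slc13a2os at 56.2 ± 25.2 (0 counts, at least 450-fold lower).

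In all, edgeR called 12697 of 18228 genes, 6700 higher and 5997 lower in model tumours (smallest adjusted p 1.41e-05), and 10563 of these had an absolute log2 fold change of at least 1. The libraries of the groups did not overlap for 76.7% of genes, where chance gives 10%. Camera called 15 of 29 tested lists, 7 higher and 8 lower, and 0 with an estimated correlation (lowest adjusted p = 0.532), whereas fry called 20. The median gene lay at 0.12 with TMM, 0.02 with RLE, 0.17 with upper-quartile factors and 0.72 without scaling factors, so directions are relative to the TMM scale. Without factors 9060 genes were higher and 4405 lower (67.3% higher, against 52.8%). With limma-trend on log2(FPKM + 1), 8107 genes were higher and 3618 lower.

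AC tumours were compared with model tumours to ask how treatment with the herb pair changed the tumour transcriptome. No gene passed the threshold in edgeR with all 6 libraries, the default filter and no covariate, so single genes are given as values. Camera called the MHC class II, MHC class I, matrix and hypoxia lists lower as sets. These calls were lost with an estimated correlation (adjusted p = 0.377, 0.565, 0.34 and 0.377). Per3, a circadian clock repressor (ENSMUSG00000028957, chromosome 4, 151003652 to 151044665), measured 46.9 ± 2.11 CPM in model and 78.6 ± 7.67 in AC tumours (SD, n = 3 each), a log2 difference of 0.74 (SE 0.101, edgeR adjusted p 0.103). Lrrtm2, a synaptic adhesion protein (ENSMUSG00000071862, chromosome 18, 35209003 to 35215024), measured 24 ± 3.45 and 7.63 ± 1.151 CPM (-1.66, SE 0.176, adjusted p 0.103). Itgax, the integrin CD11c of dendritic cells, measured 17 ± 5.15 and 5.05 ± 1.88 CPM (-1.75, SE 0.315, adjusted p 0.163), and Car9, a carbonic anhydrase induced by hypoxia, 33.2 ± 8.74 and 12.6 ± 0.502 CPM (-1.4, SE 0.195, adjusted p 0.103).

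With edgeR, 0 of 17137 genes were called (smallest adjusted p 0.103), and 2253 had an unadjusted p under 0.05 (997 higher, 1256 lower), where 857 would come from chance. A split of the same 6 libraries that mixed the groups (model tumours 1 and 3 with AC tumour 3 against the others) gave more, 2636. The groups did not overlap for 19.1% of genes, where chance gives 10%. DESeq2 called 284 genes (75 higher and 209 lower, with 2141 at an unadjusted p under 0.05), and limma-trend on log2(FPKM + 1) called 0 (2043 at an unadjusted p under 0.05). The edgeR fit of all 9 libraries called 0, with only 984 of 18920 genes at an unadjusted p under 0.05. With single libraries left out, that count in edgeR ran from 1286 (without model tumour 1) to 3788 (without AC tumour 3), so the excess depends on the fit and on single libraries. Without AC tumour 3, edgeR called 569 genes (150 higher, 419 lower), and with both libraries that carried colonic transcripts left out 94 (14 higher, 80 lower). With the colonocyte level as a covariate it called 243 (65 higher, 178 lower), and without the low-count filter 105 (23 higher, 82 lower). Next to Per3, the genes with the smallest p on the higher side were Tsc22d3, a glucocorticoid-induced leucine zipper protein (157 ± 20.9 CPM in model, 270.2 ± 32.4 in AC), Rabggtb, a subunit of a prenyltransferase (174 ± 27.5 and 287 ± 16.8), Gas6, a ligand of the TAM receptors (17.2 ± 1.89 and 30.0 ± 2.44), and Per2, another clock repressor (29.0 ± 7.73 and 63.0 ± 5.07). Next to Lrrtm2 on the lower side were Farp1 (142 ± 8.91 and 84.6 ± 5.45), Serpinf1, the secreted factor PEDF (107 ± 9.53 and 62.5 ± 5.55), Ankrd44 (56.1 ± 6.57 and 31.7 ± 2.13), and the interferon-inducible GTPase Tgtp1, uncertain because Tgtp2 is a close copy (37.5 ± 0.947 and 21.7 ± 1.5). Adjusted p of these 8 genes lay between 0.103 and 0.137.

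**Figure D3:**
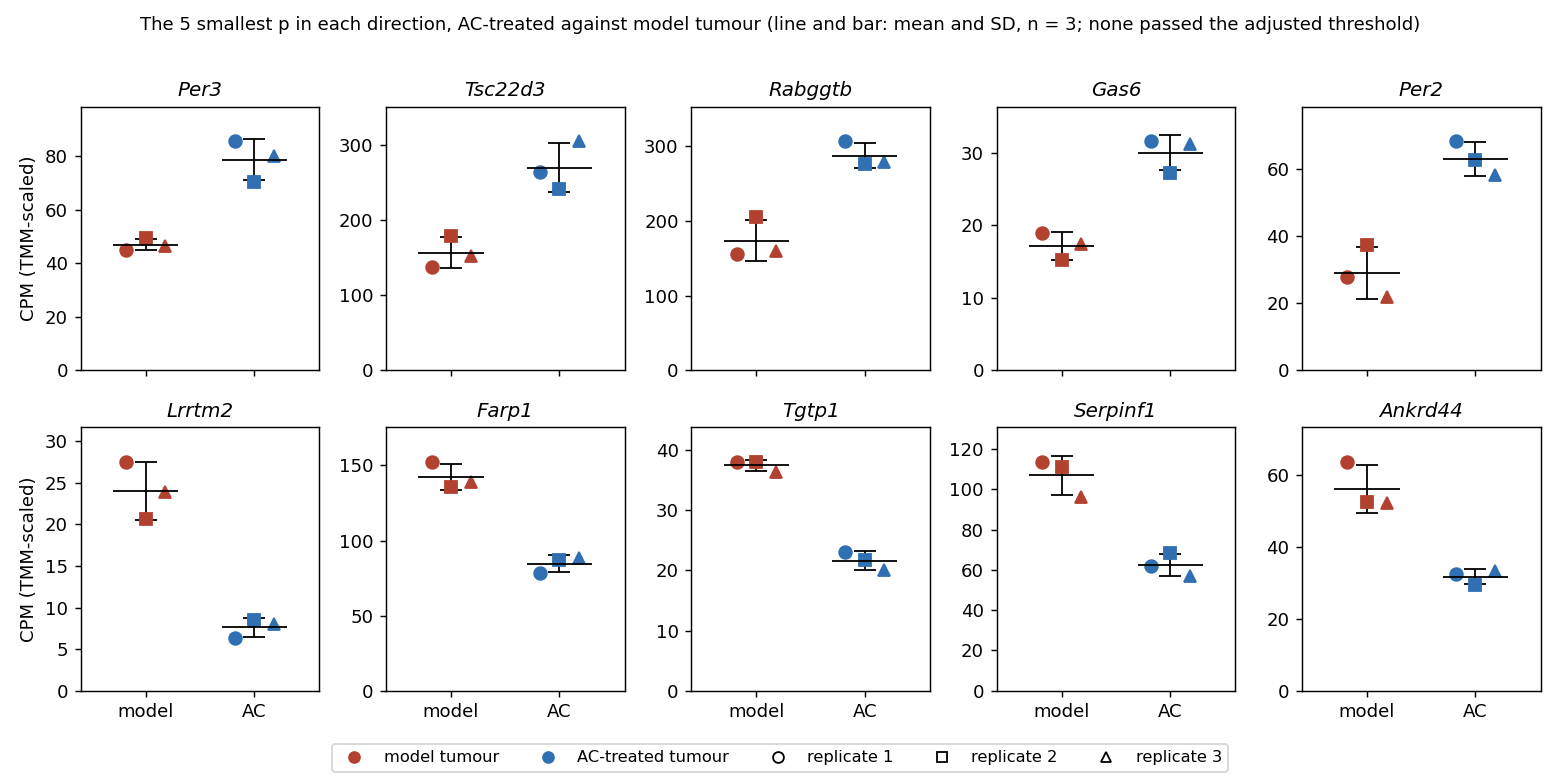
CPM per library (vertical axis) of the genes with the smallest p in AC against model tumours, with a point per library and a line at the mean of 3. Per2 lies at 29.0 CPM in model and 63.0 in AC tumours, and edgeR adjusted p is 0.103 or higher for every gene shown.

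Camera called 9 of 25 tested lists, 8 lower and 1 higher in AC tumours, and 0 with an estimated correlation (lowest adjusted p = 0.305), whereas fry called 2. Without AC tumour 2 camera called 14 lists. None of the members of any list passed over all genes in edgeR with all 6 libraries, the default filter and no covariate. Itgax, Car9, Tap1 and Hsph1 passed with DESeq2, with edgeR without AC tumour 3 and with edgeR and the colonocyte covariate. The counts that follow are of signs, and of genes adjusted over the list alone. They come from edgeR with all 6 libraries, the default filter and no covariate. All 11 dendritic cell and MHC class II genes had negative values (median -0.61, camera adjusted p 2.56e-05, and adjusted p = 0.377 with an estimated correlation), with Itgax the 1 gene lower when adjusted over the list alone. The median was -1.05 with model tumour 1 and AC tumour 3 left out. H2-Aa, a class II alpha chain, measured 92.5 ± 12.3 CPM in model and 56.4 ± 31 in AC tumours. AC tumour 3, which also held colonic transcripts, lay near the model tumours in this list, with a level of 3.51 against 2.96 and 2.78 in the other AC tumours and 3.64 to 3.82 in model tumours. All 14 interferon response genes had negative values (median -0.3, camera adjusted p 2.56e-05, adjusted p = 0.34 with an estimated correlation; 0 adjusted over the list alone). For MHC class I genes 10 of 11 values were negative (median -0.27, camera adjusted p 3.66e-05, adjusted p = 0.565 with an estimated correlation), and Tap1, the peptide transporter, the 1 gene lower when adjusted over the list alone, measured 174 ± 17.3 and 106 ± 12.8 CPM. The T and NK cell list was lower with 9 of 14 values negative (median -0.42, camera adjusted p 0.00844, adjusted p = 0.567 with an estimated correlation) and 4 genes lower when adjusted over the list alone, but it was not called without AC tumour 2 (0.161, over a range of 0.000135 to 0.161). Cd8b1, a chain of the CD8 coreceptor, measured 3.23 ± 0.333 and 1.49 ± 0.429 CPM, and Prf1 43.1 ± 6.07 and 45.3 ± 15.7 CPM.

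Fibroblast and extracellular matrix genes had 13 of 14 negative values (median -0.6, camera adjusted p 7.42e-06, adjusted p = 0.34 with an estimated correlation), with 3 genes lower when adjusted over the list alone. Pdgfrb, a receptor of mesenchymal cells, measured 107 ± 18.3 CPM in model and 61.2 ± 9.64 in AC tumours. AC tumour 3 had the highest matrix level of the AC tumours, 7.03 against 6.04 and 6.48, with 7.13 to 7.46 in model tumours. In the mesenchymal transition list 11 of 14 values were negative (median -0.44, camera adjusted p 6.75e-05, adjusted p = 0.305 with an estimated correlation, fry adjusted p 0.0375) and 6 genes were lower when adjusted over the list alone, among them Mmp14, a membrane metalloproteinase, at 151 ± 8.3 and 97.6 ± 12 CPM. Hypoxia and glycolysis genes had 14 of 15 negative values (median -0.38, camera adjusted p 7.42e-06, adjusted p = 0.377 with an estimated correlation) and 4 genes lower when adjusted over the list alone. Pdk1, a brake on pyruvate oxidation, measured 105 ± 26.2 and 62.7 ± 3.61 CPM. Of 18 cell cycle genes 15 had negative values, 1 of the 18 changing sign without scaling factors (median -0.14, camera adjusted p 0.00326, adjusted p = 0.305 with an estimated correlation, fry adjusted p 0.0296), and 3 were lower when adjusted over the list alone. Plk1, a mitotic kinase, measured 58.6 ± 3.46 and 45.8 ± 0.512 CPM. The list called higher held p53 targets, with 10 of 12 values positive (median 0.18, camera adjusted p 0.0393, adjusted p = 0.34 with an estimated correlation) and 0 genes adjusted over the list alone. It was not called without model tumour 2 (0.0718) or model tumour 3 (0.16), over a range of 0.0119 to 0.16. Bax, a pore-forming protein of apoptosis, measured 47.5 ± 3.5 and 64.4 ± 9.13 CPM, and Cdkn1a, the inhibitor p21, 148 ± 10.7 and 185 ± 21.7 CPM.

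**Figure D4:**
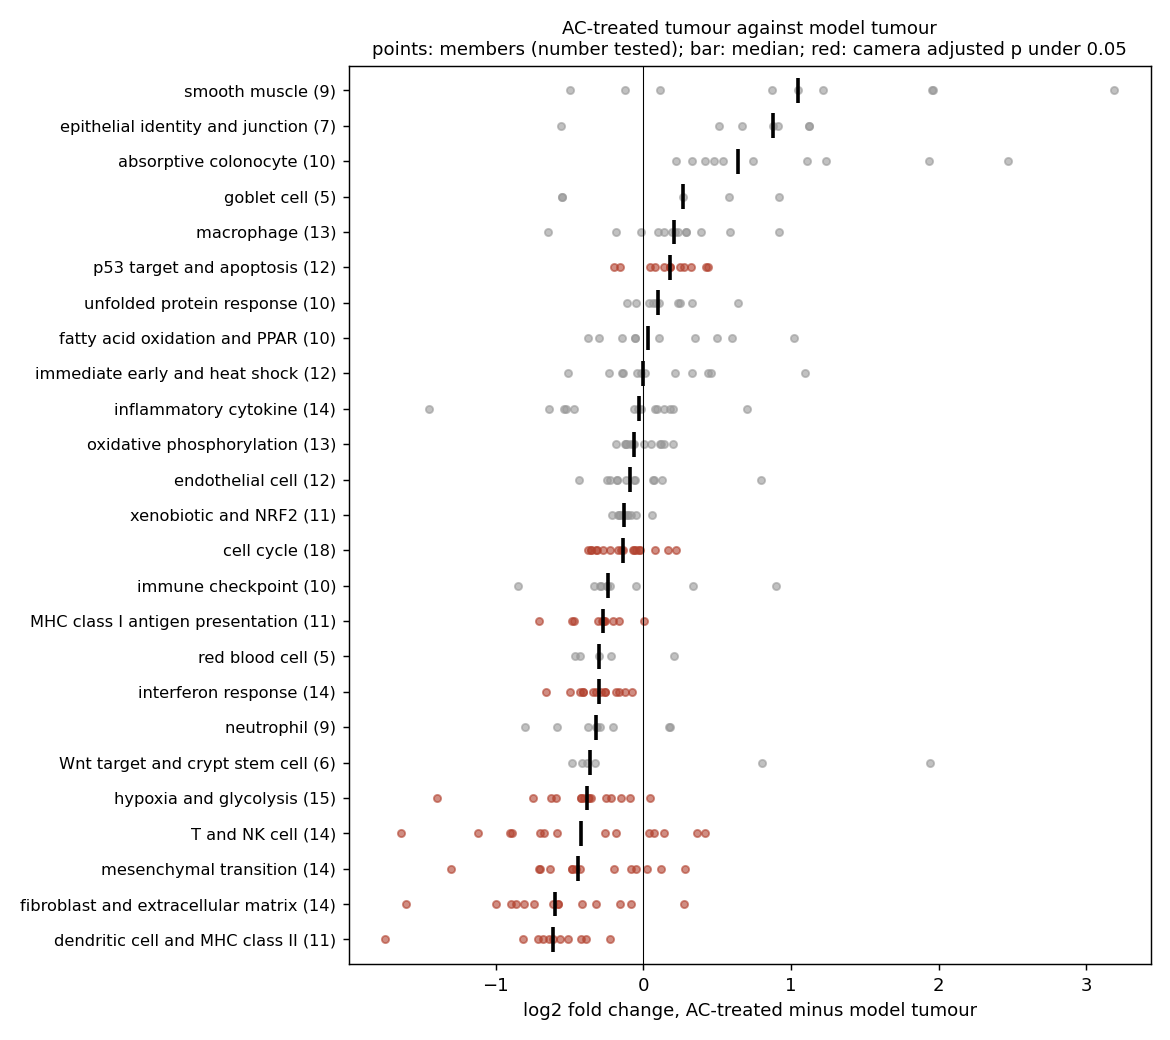
Log2 fold change of each tested member of the gene lists, AC minus model tumours (horizontal axis), with a point per gene and a line at the list median. The medians of the MHC class II and matrix lists lie at -0.61 (-1.05 with model tumour 1 and AC tumour 3 left out) and -0.6, and that of the macrophage list at 0.21.

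The other lists were not called in this comparison. Macrophage genes had a median of 0.21 (13 tested, camera adjusted p 0.144), with 1 gene changing sign without scaling factors, and Mrc1 measured 304 ± 121 CPM in model and 457 ± 165 in AC tumours. Medians and camera adjusted p were -0.32 and 0.243 for neutrophil genes (9 tested), -0.24 and 0.27 for checkpoint genes (10), -0.09 and 0.27 for endothelial genes (12) and -0.3 and 0.216 for red blood cell genes (5). They were -0.03 and 0.377 for inflammatory cytokine genes (14 tested, median 0.01 without scaling factors), -0.06 and 0.844 for oxidative phosphorylation (13), 0.1 and 0.0843 for the unfolded protein response (10) and -0.13 and 0.216 for xenobiotic and NRF2 genes (11). Immediate early and heat shock genes had a median of 0, a mean of 0.12 and a median of 0.03 without scaling factors (12 tested, 0.575), and Hsph1, a large heat shock protein, measured 254 ± 56.4 and 541.9 ± 179 CPM. Fatty acid oxidation genes had a median of 0.03 (10 tested, 0.882), with Acadm, an acyl-CoA dehydrogenase, the 1 gene higher when adjusted over the list alone (82.4 ± 9.34 and 116.6 ± 14.3 CPM). Smooth muscle genes had a median of 1.05 (9 tested, 0.216), with a level of 3.2 in AC tumour 2 against 1.82 and 2.17 in the other AC tumours. The epithelial lists followed model tumour 1 and AC tumour 3. Medians were 0.64 for absorptive colonocyte genes (10 tested, 0.326), 0.88 for epithelial identity genes (7, 0.882) and 0.27 for goblet cell genes (5, 0.527), whose mean of 0.13 and negative camera direction differed in sign. With model tumour 1 and AC tumour 3 left out, medians were 0.4 for absorptive colonocyte, 0.34 for epithelial identity, 0.06 for goblet cell, -0.02 for neutrophil, 0.19 for red blood cell, 0.2 for inflammatory cytokine and -0.2 for Wnt target and crypt genes. They were 0.19 for the unfolded protein response, -0.02 for xenobiotic and NRF2, -0.02 for endothelial, 0.11 for fatty acid oxidation, -0.01 for oxidative phosphorylation and 0.11 for immediate early genes. The Wnt target and crypt list had a median of -0.36, a mean of 0.19 and a negative camera direction (6 tested, 0.494). Fewer than 5 genes were tested of the enteroendocrine (1), enteric neuron (3), skeletal muscle (3), keratinocyte (2), adipocyte (4), acinar (1) and B and plasma cell (4) lists. The median of the B and plasma cell genes was -0.94, and 0.01 with model tumour 1 and AC tumour 3 left out.

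AC tumours were also compared with healthy colon. As in model tumours, epithelial and metabolic transcripts fell, and macrophage, matrix, mesenchymal and cell cycle transcripts rose as lists by camera with the preset correlation, and these calls were lost with an estimated correlation (lowest adjusted p = 0.536). Slc9a3 went from 347.5 ± 111 CPM in colon to 0.0825 ± 0.107 in AC tumours (log2 fold change -11.95, SE 0.752, edgeR adjusted p 5.87e-05), and Vim from 35.8 ± 18 to 2582 ± 265 CPM (6.17, SE 0.43, adjusted p 7.65e-05). Col1a1 from 9.63 ± 0.248 to 94.1 ± 3.5 CPM (3.29, SE 0.123, adjusted p 2.61e-05) and Msr1 from 4.25 ± 0.281 to 152 ± 26 CPM (5.16, SE 0.193, adjusted p 2.61e-05). Camera called 14 of 28 tested lists, 8 lower and 6 higher, and 0 with an estimated correlation, whereas fry called 23. All 14 absorptive colonocyte genes (median -7.61), all 14 epithelial identity genes (-6.71), 10 of 12 goblet cell genes (-4.4), the 6 tested enteroendocrine genes (-4.63) and the 9 B and plasma cell genes (-7.29) fell. Of the metabolic lists called lower, oxidative phosphorylation had 13 of 13 genes lower (-1.73, 1 changing sign without scaling factors), fatty acid oxidation 10 of 12 (-3.69) and xenobiotic and NRF2 9 of 12 (-1.83). Called higher were macrophage genes (12 of 13 higher, median 3.32), inflammatory cytokines (11 of 14, 3.94, with 2 changing sign without scaling factors), matrix (11 of 14, 3.3), mesenchymal transition (13 of 14, 4.37, with 1 changing sign), endothelial (9 of 12, or 10 adjusted over the list alone, 2.14) and cell cycle genes (18 of 18, 2.09). The other counts in these lists did not change when adjusted over the list alone. Not called were smooth muscle (10 of 12 lower, median -3.96, camera adjusted p 0.0525), Wnt target and crypt (6 of 10 lower, -2.74, 0.0868), interferon response (10 of 14 lower, -1.3, 0.0868), MHC class II (5 of 11 lower, 2 higher, -1.17, 0.353) and T and NK cell genes (6 of 14 lower, 3 higher, -1.15, 0.447). Hypoxia (9 of 15 lower, 4 higher, median -0.75, 0.229), MHC class I (5 of 11 lower, 1 higher, -0.27, or 0.38 without scaling factors, 0.229), p53 target (-0.67, 0.392) and immediate early genes (-0.32, or 0.34 without scaling factors, 0.392) were not called either. The same held for neutrophil (median 3.23, 0.204), checkpoint (0.17, 0.671), unfolded protein response (0.85, 0.471), enteric neuron (-1.87, 0.392) and adipocyte genes (-1.93, 0.634). The skeletal muscle, keratinocyte, acinar and red blood cell lists had fewer than 5 tested genes. In all, edgeR called 12165 of 17832 genes, 6339 higher and 5826 lower, and 75.8% of genes had groups that did not overlap (chance 10%). Without scaling factors, the median gene moved from 0.1 to 0.75 and 8832 genes were higher and 4114 lower (68.2% higher, against 52.1%). Limma-trend on log2(FPKM + 1) gave 8085 genes higher and 3463 lower.

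Whether AC treatment moved genes against their direction in the tumour was asked from genes called in both model against colon and AC against model. With edgeR this overlap held 0 genes in opposite and 0 in the same direction, because 0 genes were called in AC against model (2253 at an unadjusted p under 0.05). With the calls of DESeq2 it held 183 opposite and 50 in the same direction, and with those of edgeR without AC tumour 3, 329 opposite and 126 the same. Both comparisons share the model libraries with opposite sign, which favours opposite pairs. The simulations below called at most 1 gene in AC against model, so they give no expected split for these counts, which therefore do not show a reversal by treatment. Over 16483 genes the log2 fold changes of the comparisons had a covariance of -0.286, against -0.106 (range -0.127 to -0.0849 in 20 simulations) for AC tumours simulated without a change from the model group, a difference of -0.18. Pearson's r across genes, which are not independent replicates, was -0.271 against -0.0903 simulated. Of 11074 genes called in model against colon, 59.8% had the opposite sign in AC against model, against 53.8% simulated. The simulated values already include the model libraries shared by both comparisons, but with genes that vary independently. A shift of many genes at once in the 3 model libraries is therefore not covered. Without AC tumour 3 the covariance was -0.0826, close to the value simulated with all 9 libraries (difference 0.0233), and 54.6% of called genes had the opposite sign. The 329 opposite and 126 same-direction genes above come from this same setting. The covariance was -0.489 without AC tumour 1 (difference -0.383) and -0.486 without AC tumour 2 (difference -0.38). It was -0.668 without model tumour 1, and -0.34 (58.5% opposite) with model tumour 1 and AC tumour 3 both left out. All differences are from the value simulated with all 9 libraries, and no simulation was run with any library left out.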

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

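Upper-quartile factors, no factors, an adjusted p under 0.1, model tumour 1 and AC tumour 3 left out together and the colonocyte covariate were chosen only after the results were seen, and the other alternatives were set in advance. Genes called in model against colon (12697) ran from 10563 to 15339 over the alternatives, and those in AC against colon (12165) from 10100 to 14411. The 15339 came without sham 1, where colon was only the closely alike sham 2 and sham 3, so its spread may be understated. For AC against model, where edgeR called 0 genes, no low-count filter gave 105, DESeq2 284, both libraries left out 94, the colonocyte covariate 243 and single libraries left out 0 to 569. Genes changed in opposite directions numbered 67 without the filter, 183 with DESeq2, 62 with both libraries left out and 0 to 329 with single libraries left out. Those changed in the same direction numbered 18, 50, 16 and 0 to 126. The shared model libraries favour opposite pairs, and no expected split was available. Lists called in model against colon fell from 15 to 0 with an estimated correlation and ran from 13 to 15 with single libraries left out. Lists called in AC against model (9) fell to 0 with an estimated correlation and 2 with fry, to 0 with fry and both libraries left out, to 0 with an estimated correlation or fry beside the covariate, and ran from 9 to 14 with single libraries left out; the cause was not tested. Of 105 values of genes named in model against colon, all stayed on their side of the threshold under DESeq2, RLE, a fit of all 9 libraries and the block. With 1 library left out 623 values did so, 6 lost and 1 gained a call. Leaving both out removes only model tumour 1 from this comparison, so the 104 values that did so there repeat that setting. Of 42 in AC against model, 17 gained a call with DESeq2, 16 with the covariate, 7 with both left out and 17 of 252 with 1 left out. The replicate number as a block gave 11774, 0 and 11303 genes for model against colon, AC against model and AC against colon, 0 opposite, and 15 and 10 lists. After subtraction of group means, samples of model and AC tumours with the same number correlated at -0.57, 0.48 and -0.35. Model tumour 1 correlated best with AC tumour 3 (0.69), the libraries with colonic transcripts. These values gave no sign of pairing by number but cannot exclude it. In simulations of AC against model at the depth and group size of these samples, 50.4% of 2-fold changes were recovered.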

Other observations

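The gene groups below, the tests of explanations, the colonocyte covariate and model tumour 1 and AC tumour 3 left out together were chosen only after the results were seen, while DESeq2, single libraries left out and the splits of the libraries were set in advance. Of 12 interferon-inducible GTPase genes, most of them with close copies and so uncertain, all 12 had lower values in AC than in model tumours. None passed the threshold in edgeR with all 6 libraries, the default filter and no covariate, while Gbp4 and Tgtp2 are among the 35 genes given below. Gbp4, a guanylate-binding protein, measured 230.0 ± 10.7 CPM in model and 129.9 ± 19.4 in AC tumours (log2 difference -0.82, adjusted p 0.103), and Iigp1, an immunity-related GTPase, 231 ± 34 and 130.4 ± 10.9 CPM (-0.82, adjusted p 0.122). In model tumours against colon, Gbp4 had risen from 13.4 ± 5.08 to 184 ± 12.4 CPM and Iigp1 from 18.2 ± 5.59 to 185 ± 30 CPM, while Irgm1, another immunity-related GTPase, had fallen from 165 ± 4.97 to 107 ± 6.54 CPM. Of the clock genes, Per2 fell from 95.1 ± 4.7 to 23.3 ± 6.24 CPM in model tumours and measured 29.0 ± 7.73 in model and 63.0 ± 5.07 in AC tumours, while Arntl, the activator BMAL1, rose from 22 ± 2.08 to 42.9 ± 4.06 CPM and measured 53.6 ± 6.28 and 32.2 ± 2.86.

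For AC against model tumours, 35 genes passed with each of DESeq2, edgeR without AC tumour 3, edgeR with both libraries that carried colonic transcripts left out and edgeR with the colonocyte covariate, 7 higher and 28 lower. These settings refit the same or overlapping libraries, so their shared direction is no support. In edgeR with all 6 libraries, the default filter and no covariate, adjusted p of the 35 ran from 0.103 to 0.351. Lrrtm2, Farp1, Ankrd44 and Gbp4, given above, were among them, as was Tgtp2. Stab1, a macrophage scavenger receptor, measured 172 ± 25.7 CPM in model and 278 ± 76.9 in AC tumours (groups overlapping, adjusted p 0.299 in that fit). Col6a1, a chain of type VI collagen, measured 202 ± 7.59 and 122 ± 36 CPM (0.257), and Fst, the activin-binding protein follistatin, 90.7 ± 2.21 and 46.8 ± 14.9 CPM (0.24). The Y-linked gene Ddx3y measured 109 to 171 CPM in colon and 13.7 to 18.2 in the 6 tumours, and Eif2s3y 136 to 179 and 6.07 to 12 CPM. Of features with an identifier of the authors' own, 874 of 1005 tested were called in model against colon. In AC against model, 0 of 878 were called by edgeR with all 6 libraries, the default filter and no covariate. Of the 35 genes above, 4 are such features.

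Colonic epithelial transcripts stood out in model tumour 1 and AC tumour 3, and 2 technical explanations were tested, with no biological explanation tested. Carry-over of RNA or reads from the sham libraries would give every colonic gene a similar share of its sham level, but the share differed by a factor of 9.19 or more between the 10th and 90th percentile of 111 genes, which excludes a uniform carry-over. The same spread, against 2.68 between sham 1 and the other sham libraries, also argues against colon tissue of the sham composition. Of 41 epithelial genes, 35 (85.4%) were higher in both libraries than in the 4 other tumours, but such genes prompted the test, so it decides nothing, and gut epithelial tissue or RNA of another composition stays open.

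Per2, Per3 and Arntl had the smallest p among clock genes in AC against model tumours, and 3 explanations were tested. None of these genes passed the threshold in edgeR with all 6 libraries, the default filter and no covariate. A different time of collection or a shifted circadian phase may account for it. It was tested with 10 other clock genes, in a direction set after the results were seen. Per1, Nr1d1, Nr1d2, Dbp, Tef, Ciart, Cry1, Cry2 and Bhlhe41 were to be higher and Clock lower. That direction was seen for 9 of 10, but Clock counts among them at only -0.008 (SE 0.0934), and Nr1d1 went the other way (-0.18, SE 0.158). The fry p of 0.0908 for this signed list leaves the explanation open. A glucocorticoid response may also account for it, as 9 targets other than Tsc22d3 had a median log2 difference of 0.25 (mean 0.32, SE 0.19) against a tested value of 0.4, which leaves this open as well. These 2 explanations cannot be told apart here. Colonic material in 1 library of each group is excluded, since leaving both out left the size of the differences at 1.04 of that with all 6.

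The interferon, MHC class II, matrix and hypoxia lists were lower in AC tumours by camera with the preset correlation, but not with an estimated correlation (adjusted p = 0.34, 0.377, 0.34 and 0.377) or by fry (adjusted p 0.165 for each), and 2 explanations were tested. A lower share of all infiltrating immune cells would lower macrophage genes as well. Their median log2 difference lay 0.82 above that of the MHC class II list. The SE of 0.16 is over genes and holds no spread between libraries, so this cannot exclude a lower share. Macrophage levels of 5.95 to 6.36 in AC and 5.84 to 6.13 in model tumours argue against a fall of all immune cells alike. The other explanation was colonic material in 1 library of each group. With both libraries left out, medians were -0.31 for interferon, -1.05 for MHC class II, -0.32 for hypoxia and -0.41 for matrix. Camera with the preset correlation still called all 4 lists lower (matrix adjusted p 5.58e-08), while fry called 0 lists. The medians argue against colonic material as the whole cause. The ratio to the median with all 6 was 0.857 for hypoxia and 0.692 for matrix, so a part stays open for these lists.

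The 6 libraries of each comparison were also split into 3 and 3 in all 10 ways, which cannot give a share under 0.05. In model against colon, 1 split reached the 12697 genes called, the real one (highest other 0), and 2 splits reached the 15 lists (highest other 15). In AC against model, all 10 splits reached the 0 genes (highest other 4) and 4 reached the 9 lists (highest other 11). In AC against colon, 1 split reached the 12165 genes, the real one (highest other 0).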
